A study of Caenorhabditis elegans with 6 samples.

How the data were processed

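Messenger RNA levels were measured in whole adult Caenorhabditis elegans of the strain fer-15(b26), a temperature-sensitive mutant whose sperm cannot fertilise at the restrictive temperature, so that adults can be aged without progeny. Per the labels, eggs obtained with hypochlorite were raised at 25 °C on agar plates holding either 250 µM tyrosol or the vehicle alone, and worms were exposed from the egg stage until they were collected on day 4 of adulthood. Tyrosol, 2-(4-hydroxyphenyl)ethanol, is a phenolic alcohol of olive oil; it was added in ethanol, and ethanol stood at 0.1% in the plates of both groups. Total RNA with an integrity number above 7 was used, 50 ng was labelled by reverse transcription and in vitro transcription from the 3' end of the transcripts, and 15 µg of the biotin-labelled product was hybridised to the Affymetrix C. elegans Genome Array. There were 3 control arrays and 3 tyrosol arrays, grouped by the treatment the labels give; the labels call them replicates and the protocol speaks of biological samples, without saying from how many separate cultures they came, so p-values measure the spread between these arrays.

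The deposited values are log2 expression values, 1 per probe set and array, that the authors made with RMA (robust multiarray averaging, which subtracts background, quantile-normalises the probes between arrays and summarises each probe set), per the labels and the series' design text; the version of RMA is not given in the sources used here. The base of the logarithm was taken from the values, which run from 0.47 to 12.53; a natural or decimal logarithm of that range would exceed what the scanner can record. No scanner files were used here. The array medians lie between 2.57 and 2.61, and no pair of arrays held identical values. For arrays of this kind the number of arrays limits the precision: the median standard error of a difference between groups was 0.12 on the log2 scale.

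The table holds 22625 probe sets. The 77 control probe sets of the manufacturer were left out of the tests, which leaves 22548. Gene names were taken from the platform annotation supplied with the values and brought to current symbols through the Entrez gene number and a table of RefSeq genes (assembly WBcel235, used for names alone): 20766 probe sets name 1 gene, 887 name several and 895 name none, and no gene was named from the last 2 kinds. The genome build behind the array annotation is not given in the sources used here, so no coordinates are printed. A total of 17118 genes were measured; a gene with several probe sets is represented by the probe set with the highest mean over all 6 arrays. Probe sets with the suffix _x_at or _f_at, 1227 of them, hold probes shared with other sequences and are called cross-hybridising.

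The main test was the one the series' design text names, the rank product, which was programmed anew in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. All 9 treated-minus-control differences were ranked over the probe sets, the ranks were averaged on a log scale for each direction, and the null came from 100 permutations of the values within each array. A probe set was called at an estimated false discovery rate under 0.05 in either direction. Counts of genes that rose or fell are counts of these calls on the probe sets that represent the genes. Beside it stands limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all 22548 probe sets, called under 0.05), which also gives each log2 difference its standard error. Adjusted p-values of single genes are those of limma.

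Before the data were examined, 30 gene lists were fixed and tested with camera in limma, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists; camera with an estimated correlation and fry were run beside it. The lists cover insulin signalling and other lifespan regulators, genes raised and genes lowered by DAF-16, cytosolic chaperones, the unfolded protein response of the endoplasmic reticulum, mitochondrial chaperones, antioxidant genes, phase 1 and phase 2 detoxification, xenobiotic transporters, tyrosine metabolism, immune effectors, fat synthesis, fat oxidation, lipases and lipid-binding proteins, vitellogenins, the respiratory chain, central carbon metabolism, ribosomal proteins, the proteasome, autophagy and lysosome, cuticle collagens, sperm, oocyte and germ line, cell cycle and DNA replication, body wall muscle, neurons, intestine, epidermis and pharynx. 26 list names matched no gene name of the annotation or the gene table, fer-15 itself among them, and of the 1983 list members that matched, summed over the lists, 208 had no probe set of their own and 1775 were measured. A scan without choice of genes applied camera to the 233 name-prefix families of at least 8 genes. Lists of zygotic embryo genes and of male soma genes were written only after the called genes had been seen. List medians were also set against 10000 random gene sets matched on mean level.

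The genes named in the text follow a rule fixed before the data were examined: the 12 largest increases and 12 largest decreases among genes that the rank product called and whose 3 tyrosol values all lie on the same side of the 3 control values (with fewer than 8 in a direction, genes of lowest false discovery rate up to 8, said not to pass where so); up to 4 called members of each list, or, with none called, the member of lowest limma p; and fer-15, daf-2, daf-16, hsf-1, skn-1, sod-3, hsp-16.2, gst-4, tatn-1 and vit-2 where measured. This gave 64 genes. All measured genes named outside these 64 were chosen after their values were seen. In the Results these are ssp-16, gsp-3, nspd-2, nspd-4, ssq-3, sqt-3 and sqst-1. They also include msp-33, msp-3, msp-45, msp-49, msp-50, msp-64, spe-39, spe-48, spe-5 and spe-44.

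The replicate numbers in the labels were checked for pairing before the fits were compared. The deviations from the group means of the arrays with the same number correlated across probe sets at 0.11 for replicate 1, 0.37 for replicate 2 and 0.26 for replicate 3, each over 0.1, so the numbers were treated as pairing the arrays. This comes from the values, since the labels do not say what the numbers share, and control replicate 3 correlated as much with tyrosol replicate 1, at 0.275. The 3 correlations are not separate evidence, because the deviations within a group sum to 0. A deviation shared by the replicate 2 arrays alone tends to raise the correlations among the replicate 1 and 3 arrays. The pairing is therefore not established, and results with the block depend on it. The replicate number as a block was an alternative, and the main tests are without it.

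Both tests were tested on simulated data with 3 arrays per group. The 22548 probe sets had the real means and the spreads that limma estimated, and each was drawn independently of the others. Of these, 80 were changed by 0.5, 60 by 1 and 60 by 2 on the log2 scale, besides the members of 3 shifted lists. Of changes of 0.5 on the log2 scale the rank product recovered 18.8% and limma 38.8%, of changes of 1 it recovered 96.7% and limma 95%, and of changes of 2 both recovered 100%. Of 22228 unchanged probe sets the rank product called 20 among its 155 calls and limma called 8 among 160, so that the rank product's false share in the simulation was above its nominal level. Camera called 3 of 3 simulated lists shifted by 0.3 and 0 of 27 unshifted lists. Since the simulated probe sets varied independently, this does not show how camera behaves where the genes of a list move together.

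Alternatives planned before the data were examined were quantile normalisation of the table, centring of each array on its median, the upper part of probe sets by mean level, 1 probe set per gene, the mean of a gene's probe sets, the replicate block, a stricter false discovery rate of 0.01, another random seed, limma with a trended and robust prior or with array weights, and leaving out each array in turn. Alternatives chosen after seeing the data were to leave out cross-hybridising probe sets, to leave out both replicate 2 arrays, and to use the 3'-to-5' difference of the poly-A control transcripts as a covariate; the labels do not say how these controls were added. Of 5 poly-A controls and 5 worm transcripts with 3', middle and 5' probe sets, lys, trpn and gly14 were left out of that difference because their mean 3' level was not above 4 on the log2 scale.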

Results

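Expression was compared between fer-15(b26) worms raised on tyrosol and on vehicle, 3 arrays each, on day 4 of adulthood. The series title ties tyrosol to a longer lifespan, and the comparison asks which transcripts differ in worms that received it. The 6 arrays correlated with one another over all probe sets, with a mean r per array between 0.991 and 0.995. Tyrosol replicate 2 stood farthest from the rest: the SD of its deviations from its group mean was 0.21 on the log2 scale, against 0.11 to 0.15 for the other 5 arrays. Over 3 poly-A control transcripts, bacterial sequences that are commonly added to RNA before labelling, the probe set at the 3' end exceeded the middle one by 2.18 on that array and by 1.11 to 1.53 on the others. These are the 3 of 5 poly-A controls with a mean 3' level above 4; over all 5 the difference was 1.38 against 0.78 to 1.02, and the fainter lys went the other way, at 0.37 against 0.49 to 1.05.

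**Figure D1:**
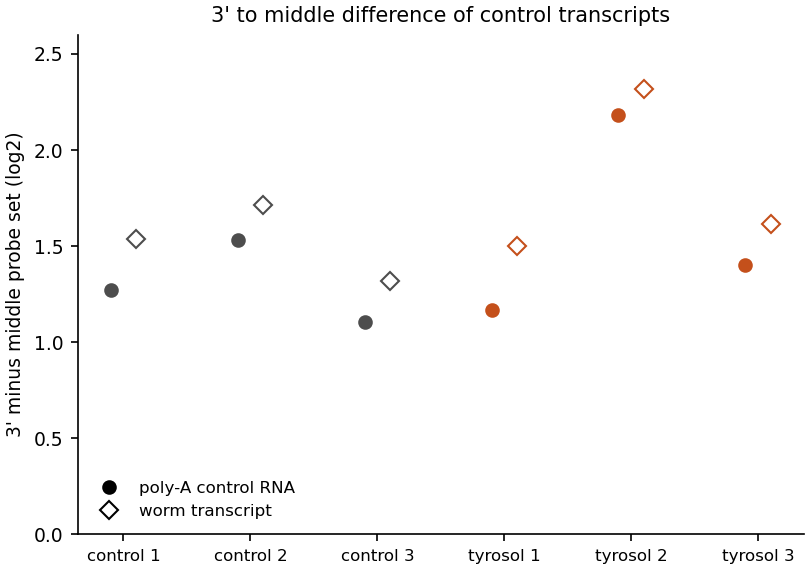
Difference on the log2 scale between the 3' and the middle probe set, averaged over 3 poly-A control RNAs (filled circles) and 4 worm transcripts (open diamonds), for each array; controls are grey and tyrosol arrays orange. Tyrosol replicate 2 lies at 2.18 and 2.32, above the other 5 arrays, which reach 1.53 and 1.71.

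The rank product called 26 of 78 sperm genes higher in worms on tyrosol, mostly major sperm protein genes read on cross-hybridising probe sets. Single genes of the epidermis, the cuticle, neurons and the immune response were called higher too, and few transcripts passed as lower. These were 4 of 83, 1 of 146, 2 of 60 and 4 of 285 genes, beside 148 of all 17118 genes called higher. With all arrays none of these 4 lists passed as a list. As a list the sperm genes passed with a preset correlation and not with an estimated one (adjusted p = 0.29). The rank product called 216 of the 22548 probe sets, 209 higher and 7 lower with tyrosol. The called increases ran from 0.62 to 2.15 on the log2 scale with a median of 0.90, a 1.86-fold rise. They name 164 genes, of which 148 were called on the probe set that represents the gene, and the decreases name 5 genes. Of the called probe sets 28 name no single gene, and 62 of those called higher are cross-hybridising. Limma called 76 probe sets, 74 higher and 2 lower, of which 73 were also called by the rank product. A total of 163 passed in limma with the replicate number as a block, 158 higher and 5 lower. Of the 29 named genes that the rank product called, limma called 2, and 17 with the block. Over all probe sets, 13.4% had their 3 tyrosol values wholly above or below the 3 control values, where chance gives 10%. Of these 1522 were higher and 1497 lower, nearly equal numbers beside the 209 and 7 called. The rank product count fell to 110, 130 and 94 without tyrosol replicate 1, 2 and 3, and to 108 without both replicate 2 arrays. Limma called 0 probe sets without control replicate 1, control replicate 3, tyrosol replicate 1 or tyrosol replicate 3, where the rank product called 174, 174, 110 and 94 and where 1281, 1228, 1707 and 1581 probe sets had an unadjusted limma p under 0.05. Chance alone gives a share of 0.05 of the 22548 probe sets under that threshold, both directions together. The counts of 1281 and 1228 lie little above it.

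**Figure D2:**
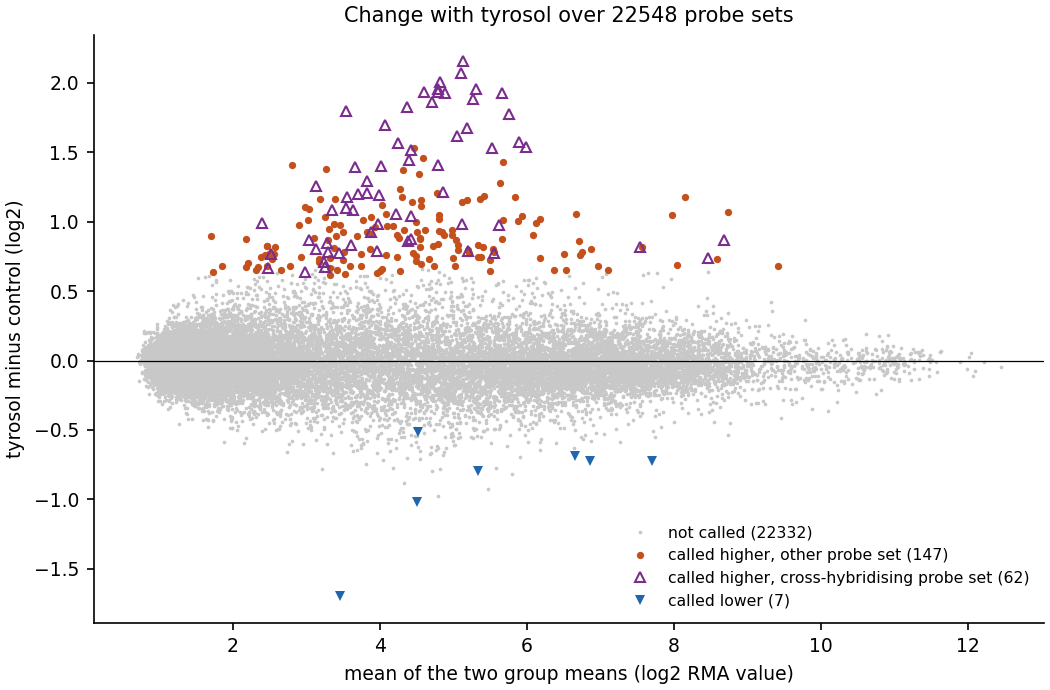
Tyrosol minus control on the log2 scale (vertical) against the mean of both group means (horizontal) for 22548 probe sets, with the 216 called by the rank product in colour; open triangles are cross-hybridising probe sets. Of the called probe sets 209 lie above 0 and 7 below.

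The major sperm proteins, the cytoskeletal proteins that drive the crawling of nematode sperm and that also signal to oocytes, held the largest increases. Of 23 measured msp genes 22 were called higher, and all 23 had every tyrosol value above every control value. The median difference of the 23 was 1.53 on the log2 scale. Among the named genes the largest increase was that of msp-77, which went from 3.82 ± 0.95 in control worms to 5.82 ± 0.14 in tyrosol worms (log2, SD, n = 3 each), a 4.01-fold rise. On the log2 scale msp-19 rose by 1.93, msp-31 and msp-78 by 1.92 each, msp-55 by 1.88, msp-36 by 1.86 and msp-76 by 1.83. The rises of msp-38, msp-53, msp-40, msp-65 and msp-59 lay between 1.53 and 1.80. The estimated false discovery rate of these 12 genes was at most 0.00065. Their limma adjusted p ran from 0.050 to 0.173, and with the replicate block from 0.029 to 0.125, under 0.05 for 5 of the 12. Limma did call other msp genes with smaller rises of 1.06 to 1.45, named after their values were seen. These were msp-33 (adjusted p = 0.025) and msp-3, msp-45, msp-49, msp-50 and msp-64 (adjusted p = 0.026 each). The controls themselves differed: msp-77 read 3.12, 4.90 and 3.43 in control replicates 1, 2 and 3, against 5.76, 5.73 and 5.97 in the tyrosol replicates.

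Outside the msp genes, 4 more members of the sperm list rose, and they are named here after their values were seen. They were ssp-16 of the sperm-specific family class P, the sperm protein phosphatase gene gsp-3, and the small peptide genes nspd-2 and nspd-4. In all, 26 of the 78 measured sperm genes were called higher and 0 lower, while 62 differed by more than 0 and 16 by less. The list's mean difference was 0.53 and its median 0.24 on the log2 scale. Limma called 8 of the 78 over all genes tested and 29 adjusted over the list alone, 28 of them higher. Camera placed the list above other genes (adjusted p = 4.8e-22), a call that was lost with an estimated correlation (adjusted p = 0.29) and with fry (adjusted p = 0.12). The list's mean level relative to the control mean was -0.12, 0.22 and -0.097 in control replicates 1, 2 and 3, and 0.48, 0.57 and 0.54 in the tyrosol replicates (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). Of the 26 genes that rose, 25 were read on cross-hybridising probe sets, on which near-identical copies cannot be told apart. The exception was ssp-16, which rose by 1.01 (SE 0.14, limma adjusted p = 0.034). The 29 measured spe genes, which act in sperm formation and activation and were read on other probe sets, had a median difference of 0.018. The rank product and limma called 0 of them. Of all probe sets, 1652 had an unadjusted limma p under 0.05 in either direction, where chance alone gives a share of 0.05. Their median control level was 1.74 on the log2 scale, below the median of each array. A rise could be hidden at such low signal, so little can be read from the faint ones. The most abundant, spe-39, spe-48, spe-5 and spe-44, read 5.02 to 7.08 in control worms. They differed by -0.12 (SE 0.15), 0.083 (SE 0.088), -0.28 (SE 0.091) and -0.27 (SE 0.12), so at these no rise like that of the msp genes was seen. Without cross-hybridising probe sets the list's mean was 0.080 (camera adjusted p = 0.030; over 15 settings it ran from 2.9e-28 to 0.030). One gene called on a probe set that does not represent it, the cross-hybridising ssq-3, is not among the 26.

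**Figure D3:**
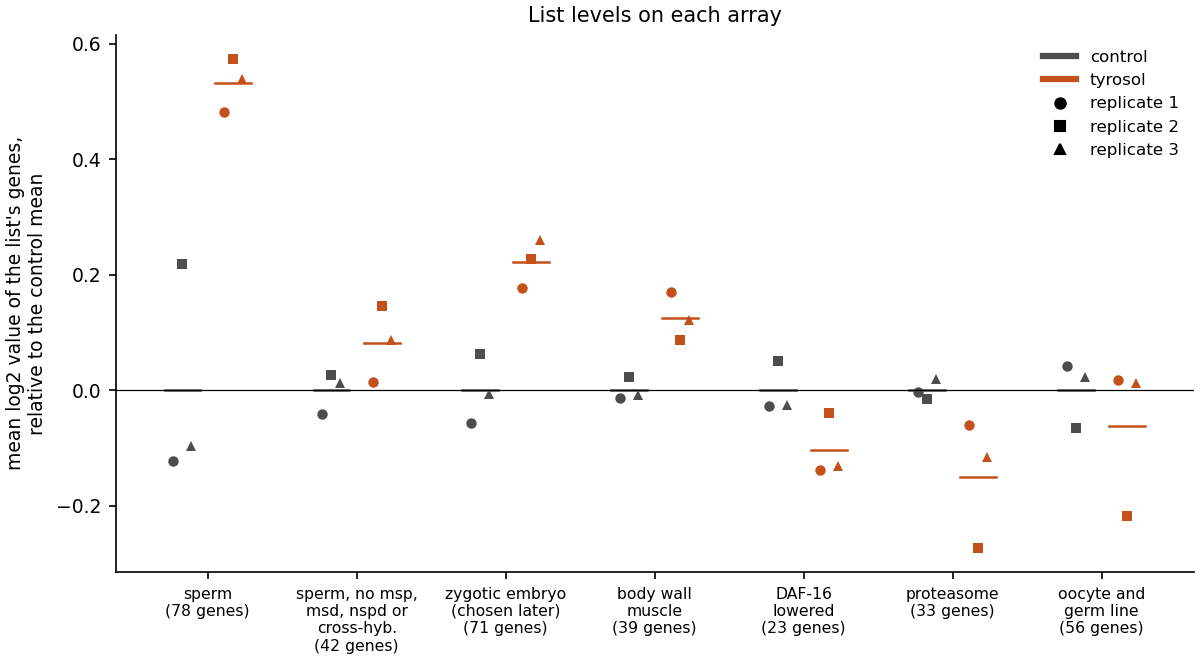
Mean log2 value of the genes of 7 lists on each array, relative to the control mean; controls are grey, tyrosol arrays orange, symbols mark the replicate number and bars the group mean. The 3 tyrosol arrays lie between 0.48 and 0.57 for sperm genes, and control replicate 2 lies between them and the other controls.

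Genes of the epidermis and its cuticle were the next group with called members. In the epidermis list 4 of 83 genes rose: mlt-11, a moulting gene, by 1.17 (SE 0.18), noah-1 and noah-2, components of the embryonic apical matrix, by 0.86 (SE 0.16) and 0.83 (SE 0.13), and wrt-10, a hedgehog-related gene, by 0.74 (SE 0.13). Limma called noah-2 alone over all genes (adjusted p = 0.0499) and 4 genes adjusted over the list alone. With the replicate block all 4 passed over all genes (adjusted p = 0.046 for mlt-11, 0.032 for noah-1, 0.020 for noah-2 and 0.033 for wrt-10). The other 79 did not pass, the list's mean was 0.058 and its median -0.0025, and camera did not call it (adjusted p = 0.20). In the upper part of mean levels it passed as higher, at 0.17 (adjusted p = 0.00067). That call rests on the preset correlation. Over all levels the list's adjusted p was 0.71 with an estimated correlation and 0.59 with fry. The call of mlt-11 held without each array in turn, and those of noah-1, noah-2, wrt-10 and dpy-14 were lost without any 1 of the tyrosol arrays, that of wrt-10 also without control replicate 1. Among 146 cuticle collagens and related genes, dpy-14 rose by 0.92 (SE 0.16); the list had a mean of 0.0064 and a median of -0.0081 (camera adjusted p = 0.75), with 0 genes called by limma over all genes, 1 adjusted over the list alone, and dpy-14 with the replicate block (adjusted p = 0.023). The collagen list's mean lay between -0.078 and 0.073 without single arrays and passed as higher without control replicate 2 or tyrosol replicate 1 (adjusted p = 0.037 and 0.035). It passed as lower with the 3'-to-5' difference of the poly-A controls as a covariate, at -0.10 (adjusted p = 0.015). A probe set of the collagen gene sqt-3 other than the one that represents it was called higher, at 0.77 (SE 0.19).

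Of 285 immune effector genes 4 rose. These were the C-type lectin genes clec-266, by 1.07 (SE 0.13, limma adjusted p = 0.026), clec-60, by 1.06 (SE 0.23), and clec-196, by 0.76 (SE 0.23), and the infection response gene irg-2, by 0.75 (SE 0.26), whose tyrosol and control values overlapped. The call of clec-266 held without each array in turn, that of clec-60 was lost without tyrosol replicate 3, and those of clec-196 and irg-2 were lost without any 1 array other than control replicate 2, with differences from 0.50 to 0.93 and from 0.54 to 1.02. The list as a whole had a mean of -0.033 and was not called (camera adjusted p = 0.24), but it passed as lower without tyrosol replicate 2, at -0.098 (adjusted p = 9.2e-05), and without both replicate 2 arrays (adjusted p = 0.0085). These calls rest on the preset correlation, and with an estimated one on all arrays the camera adjusted p was 0.95. Without single arrays its mean ran from -0.098 to 0.013, across 0. Limma called 1 gene over all genes and 1 adjusted over the list alone. With the replicate block clec-196 and irg-2 passed too (adjusted p = 0.033 and 0.041). In the neuronal list 2 of 60 genes rose, flp-15, which encodes FMRFamide-like peptides, by 1.21 (SE 0.33) on a cross-hybridising probe set, and tbb-4, a beta-tubulin of ciliated sensory neurons, by 0.74 (SE 0.14); the list's mean was 0.064 (camera adjusted p = 0.17). This list passed as higher without tyrosol replicate 2, at 0.091 (adjusted p = 0.020), and without both replicate 2 arrays, at 0.11 (adjusted p = 0.0085). The call of flp-15 was lost without tyrosol replicate 2, and that of tbb-4 without control replicate 2, tyrosol replicate 1 or tyrosol replicate 3. In limma both passed with the replicate block (adjusted p = 0.015 and 0.025) and not without it (0.32 and 0.11). Of 49 genes of fat oxidation, acs-2, an acyl-CoA synthetase of mitochondrial beta-oxidation, was called higher at 0.76 (SE 0.36) with overlapping groups and a limma adjusted p of 0.73. Without control replicate 2, which read 5.42 against 6.80 and 6.83 in the other controls, acs-2 differed by 0.29 and was not called; without tyrosol replicate 1 or 3 it was not called either. The fat oxidation list's mean was -0.0093 (camera adjusted p = 0.79).

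Decreases were few. B0024.4 fell by 1.02 (SE 0.22), C14C6.5 fell by 0.73 (SE 0.17) and F01D5.5 fell by 0.69 (SE 0.12), each with all tyrosol values below all control values and with limma adjusted p of 0.15, 0.20 and 0.082. With the replicate block the last 2 passed, at 0.036 and 0.044. F49E12.10 and the cross-hybridising F41F3.3 were called lower at -1.70 (SE 0.60) and -0.51 (SE 0.41), with overlapping groups. Single arrays set both values: F49E12.10 ran from -2.54 without control replicate 2 to -1.18 without control replicate 3, and F41F3.3 from -1.09 without tyrosol replicate 2 to -0.22 without tyrosol replicate 3. F49E12.10 lost its call without control replicate 1 or 3, B0024.4 without these or tyrosol replicate 3, and the other 3 genes without any 1 array other than tyrosol replicate 2. The lectin gene clec-71, at -0.75 (SE 0.13), the collagen gene dpy-5, at -0.59 (SE 0.17), and D1086.9, at -0.65 (SE 0.092), did not pass the rank product with all arrays. Without tyrosol replicate 2 they passed (false discovery rates 0.048, 0.0057 and 0.040), and clec-71 also without tyrosol replicate 1 (0.039). D1086.9 passed in limma (adjusted p = 0.038), and clec-71 passed the rank product with the replicate block (false discovery rate 0.041). Another random seed of the permutations gave 2 probe sets called lower in place of 7, so at most 2 of the 5 genes called lower kept their call with it. Without control replicates 1, 2 and 3 in turn the rank product called 0, 2 and 0 probe sets lower, and without tyrosol replicates 1, 2 and 3 it called 11, 28 and 2. Beside both counts of 0 limma called 0, with 1281 and 1228 probe sets at an unadjusted p under 0.05. These include both directions and lie little above the share of 0.05 that chance gives.

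**Figure D4:**
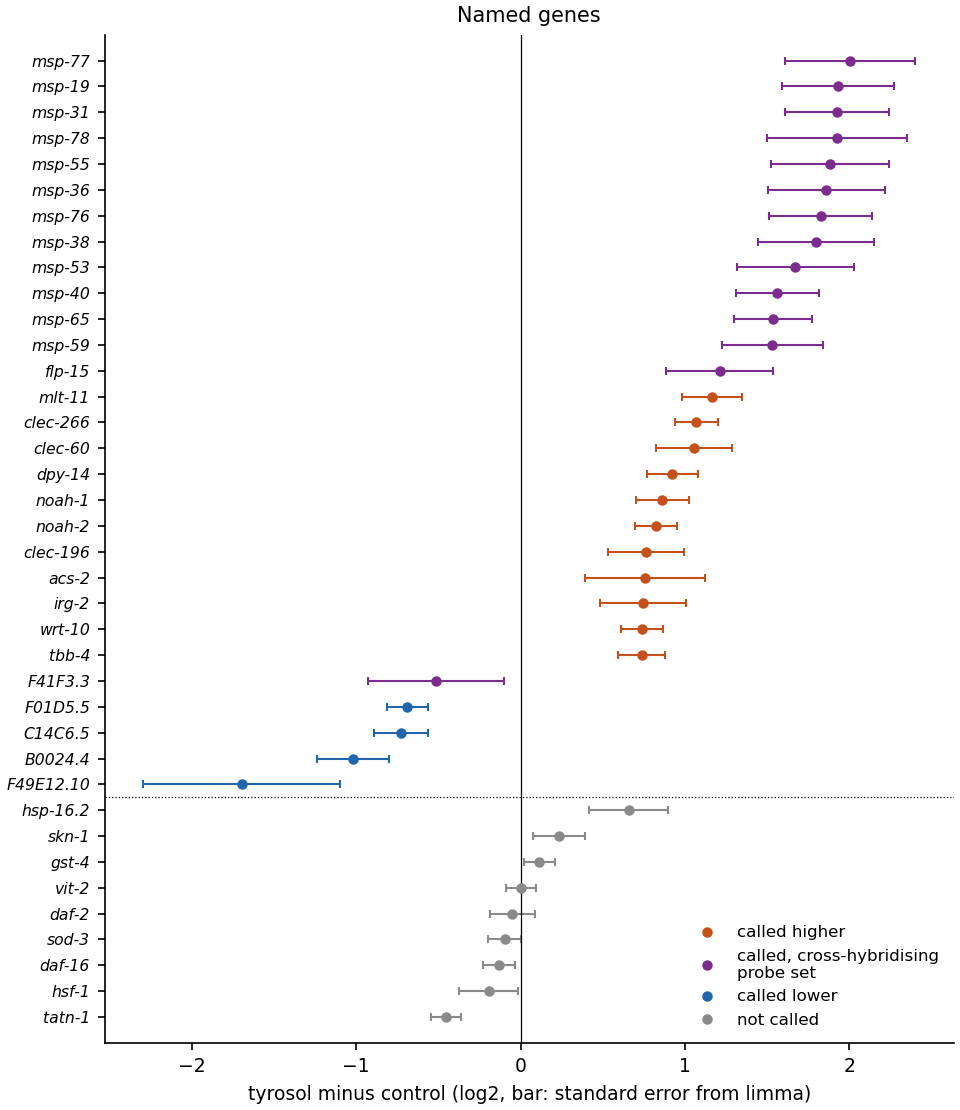
Tyrosol minus control on the log2 scale for the named genes that the rank product called (above the dotted line) and for 9 genes named in any case (below it), 3 arrays per group; bars are standard errors from limma. The 12 msp genes lie between 1.53 and 2.00, and the 9 genes below the line, none of them called, between -0.45 and 0.66.

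Genes of body wall muscle were slightly higher as a group and genes of the proteasome slightly lower, with no single gene called in either. The 39 muscle genes had a mean difference of 0.13 and a median of 0.13 on the log2 scale, and 31 were above 0. With the mean of a gene's probe sets the list's mean was 0.078 and its median 0.069. The member of lowest limma p, the actin gene act-4, differed by 0.35 (SE 0.087, adjusted p = 0.25). Camera called the list (adjusted p = 6.6e-06), and the call was lost with an estimated correlation (adjusted p = 0.13) and with fry (adjusted p = 0.12). The 33 proteasome genes had a mean of -0.15 and a median of -0.14, and 30 were below 0; rpn-6.2, a subunit of the regulatory particle, differed by -0.36 (SE 0.12, adjusted p = 0.52). Camera called this list too (adjusted p = 2.4e-05), and the call was lost with an estimated correlation (adjusted p = 0.67) and with fry (adjusted p = 0.35). Tyrosol replicate 2, the array with the large 3' difference in its control transcripts, had the lowest proteasome level at -0.27, against -0.061 and -0.12 in tyrosol replicates 1 and 3; without it the mean difference was -0.088 (camera adjusted p = 0.020; over 15 settings with the preset correlation it ran from 4.0e-07 to 0.039). Limma called 0 of the 39 and 0 of the 33 genes both over all genes and adjusted over the list alone, and the rank product called 0. Over all 22548 probe sets 1652 had an unadjusted limma p under 0.05 in either direction, where chance alone gives a share of 0.05.

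Well-known regulators of lifespan were not called, though daf-2 and hsf-1 were read on cross-hybridising probe sets. That of daf-2 read 2.40 in control worms, below the median of each array, so little can be read from it. The insulin receptor gene daf-2 differed by -0.049 (SE 0.14), its target transcription factor gene daf-16 by -0.13 (SE 0.096), the heat-shock factor gene hsf-1 by -0.19 (SE 0.18), and skn-1, which controls oxidative stress genes, by 0.23 (SE 0.16). Without single arrays daf-2 ran from -0.14 to 0.10, hsf-1 from -0.35 to 0.029 and skn-1 from 0.12 to 0.41, and none was called. Among genes that report on these pathways, the superoxide dismutase gene sod-3 differed by -0.097 (SE 0.10), the glutathione transferase gene gst-4 by 0.11 (SE 0.095) and the yolk protein gene vit-2 by 0.0015 (SE 0.092). The small heat-shock gene hsp-16.2 stood at 0.66 (SE 0.24) with a false discovery rate of 0.066, and passed with the replicate block at 0.033; without tyrosol replicate 2, the highest array, it stood at 0.35 and was not called. Of tatn-1, the tyrosine aminotransferase that opens tyrosine breakdown, the difference was -0.45 (SE 0.092, limma adjusted p = 0.13).

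No other list was called with all arrays. The 34 insulin signalling and lifespan genes had a mean of 0.070 (camera adjusted p = 0.062), with smk-1 at 0.33. They passed as higher without control replicate 1, at 0.095 (adjusted p = 0.0063). The 23 genes lowered by DAF-16 had a mean of -0.10 (adjusted p = 0.062), with dod-24 at -0.30, and this list passed in camera with the replicate block (adjusted p = 0.042; over 15 settings it passed in 5 and ran from 0.0061 to 0.22). With all arrays its adjusted p was 0.67 with an estimated correlation and 0.37 with fry. Without tyrosol replicate 2 the adjusted p was 0.0061. The 24 genes raised by DAF-16 had a mean of 0.011 and a median of -0.016, with hsp-12.3 at 0.43. Cytosolic chaperones, 26 genes, had a mean of 0.089 (adjusted p = 0.075), with hsp-16.41 at 0.52; they passed as higher without control replicate 1, at 0.11 (adjusted p = 0.028), and without tyrosol replicate 3, at 0.12 (adjusted p = 0.014). The unfolded protein response of the endoplasmic reticulum, with xbp-1 at 0.26, and the mitochondrial chaperones, with atfs-1 at -0.55, had means of -0.020 and -0.048; without tyrosol replicate 2 atfs-1 stood at -0.19. For antioxidant genes, with gpx-3 at 0.41, the mean was 0.0074 and the median -0.015.

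Detoxification and metabolism were likewise not called as lists. The means were -0.032 for 121 phase 1 genes, with dhs-24 at -0.42, 0.0073 for 110 phase 2 genes, with ugt-43 at 0.39, and -0.012 for 49 xenobiotic transporters, with mrp-5 at 0.32. Tyrosine metabolism, 19 genes, had a mean of 0.021, and 1 gene, tatn-1 at -0.45, passed as lower in limma adjusted over the list alone. Fat synthesis had a mean of -0.0083 and a median of 0.015, with mdt-15 at -0.59. Lipases and lipid-binding proteins had a mean of 0.012, with lipl-7 at 0.55 as the 1 gene that passed adjusted over the list alone. The 5 vitellogenins, with vit-4 at -0.11, had a mean of -0.025, the respiratory chain, with cyc-2.2 at 0.47, a mean of 0.0050, and central carbon metabolism, with tps-1 at 0.32, a mean of -0.030. Ribosomal proteins, with rpl-10L at 0.14, had a mean of -0.0010, and autophagy and lysosome genes, with vps-34 at 0.33, a mean of 0.0021 and a median of -0.011. In the autophagy list a probe set of sqst-1 other than the one that represents it was called higher, at 0.68 (SE 0.16).

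Among the tissue and cell cycle lists, the 56 oocyte and germ line genes had a mean of -0.063, with pgl-3, a P granule gene, at -0.26, and the 48 cell cycle genes a mean of -0.0054, with orc-2 at 0.28. The oocyte level on tyrosol replicate 2 was -0.22, against 0.017 and 0.012 on the other tyrosol arrays. The oocyte list passed as lower without control replicate 2 or tyrosol replicate 1 (adjusted p = 0.037 and 0.039). The intestine list had a mean of -0.049, with the intestinal transcription factor gene elt-2 at -0.29. The pharynx list had a mean of 0.051, with the junction gene ajm-1 at 0.62, which passed the rank product with the replicate block (false discovery rate 0.037) and in limma with the block (adjusted p = 0.042) or adjusted over the list alone. Another probe set of ajm-1, with lower signal, was called higher with all arrays, at 0.63 (SE 0.10, false discovery rate 0.047). The pharynx list passed as higher without tyrosol replicate 2, at 0.079 (adjusted p = 0.020), and without both replicate 2 arrays (adjusted p = 0.046), and in the upper part of mean levels, at 0.16 (adjusted p = 0.0058). Mean and test differed in sign for fat synthesis, central carbon metabolism, ribosomal proteins, cell cycle and the unfolded protein response of the endoplasmic reticulum, whose means were below 0 while camera ranked them above other genes. The camera adjusted p of the 27 lists that did not pass ran from 0.062 to 0.93, and with an estimated correlation from 0.67 to 0.95. For 17 of these lists the mean changed sign when single arrays were left out. Among them were central carbon metabolism (-0.063 to 0.028), the unfolded protein response of the endoplasmic reticulum (-0.049 to 0.0078), vitellogenins (-0.048 to 0.017), tyrosine metabolism (-0.0012 to 0.050) and oocyte and germ line genes (-0.10 to 0.015).

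In the scan over 233 name-prefix families, 5 were higher with tyrosol and 0 lower. The msp family led, with a mean difference of 1.44 on the log2 scale. The 95 fbxb genes, which encode F-box proteins, had a mean of 0.18 (adjusted p = 1.4e-10), with 29 genes wholly above their control values and 4 called by the rank product. The related fbxc family, 44 genes, had a mean of 0.13 (adjusted p = 0.035), the 8 ssp genes a mean of 0.33 (adjusted p = 5.4e-05) and the 14 spig genes a mean of 0.18 (adjusted p = 0.019). All 5 calls were lost with an estimated correlation (adjusted p = 0.96) and with fry, where the adjusted p ran from 0.17 to 0.56. With the replicate block the kin family, higher, and the mrpl family of mitochondrial ribosomal proteins, lower, also passed (adjusted p = 0.049 each, against 0.05001 each without it, and 0.96 and 0.98 with an estimated correlation). Beside 0 families called lower, 1652 probe sets had an unadjusted limma p under 0.05 in either direction, where chance alone gives a share of 0.05.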

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

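Apart from the counts over splits of the arrays, the tests here were chosen after the patterns they bear on had been seen, and those of loss during labelling, of RNA degradation and of embryos also after the values they use. The 3'-minus-middle difference of the control probe sets, which enter no comparison, was higher on tyrosol replicate 2 than on the other 5 arrays, at 2.18 for 3 poly-A control RNAs and 2.32 for 4 worm transcripts (over all 5 of each, faint ones included, 1.38 and 2.01, where the highest others were 1.02 and 1.54). The poly-A controls are not worm RNA, so degradation of the worm RNA alone would leave them in the range of the other arrays, whose highest is 1.53 and whose SD is 0.17; at 2.18 they argue against it. Loss of the 5' part during labelling may account for the array's distance from the rest, with a mean r of 0.991, since it needed the poly-A controls to be that high. Their 3'-minus-5' difference stood out less, at 3.39 against at most 3.08 on the other arrays. That of thr, at 2.49, lay within the 2.04 to 2.76 of the others. The 3' levels of dap, phe and thr were also lowest on this array, at 6.06, 4.26 and 4.14. An uneven addition of these controls and a biological difference of this array stay open as untested.

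Sperm transcripts were higher on all 3 tyrosol arrays than on all 3 control arrays. Of the technical explanations, signal shared between near-identical msp probe sets was tested on 42 sperm genes. These lie outside the msp, msd and nspd genes and outside cross-hybridising probe sets. Their median difference was 0.046, above 99.2% of 10000 matched sets. The rule written before these values were used asked for a median above 95% of matched sets, which was met and goes against this explanation. But the array means, which that rule left out, overlapped (two-sided exact permutation p = 0.2). So how many genes rose cannot be told apart from a rise of few that many probe sets read. Only 14 of the 42 lie above the median level of all genes, which limits this test further. Embryos or other offspring among the treated worms may carry other transcripts with them. The 71 zygotic embryo genes had a median of 0.086, above 100% of matched sets. Their means were higher on all 3 tyrosol arrays than on all 3 control arrays (two-sided exact permutation p = 0.1, the smallest possible). But the list was written after its 11 called members had been seen. Without these members the other 60 had a median of 0.052, above 99.8% of matched sets, with overlapping array means (two-sided exact permutation p = 0.2). The list holds no member of the sperm list, so it does not test the sperm rise itself, and this explanation stays open. Males could bring sperm too, and the 20 male soma genes had a median of -0.028, but only 5 of them lie above the median level of all genes, which leaves this open. An effect of tyrosol on sperm formation or on its timing is the biological explanation the design gives, and it stays open as untested.

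Proteasome genes were lower on the tyrosol arrays, most on tyrosol replicate 2. Without that array the list's mean difference was -0.088 against -0.15 with it, which is more than 50% of it by less than the SD of 0.039 between tyrosol replicates 1 and 3. The rule written before these values were used asked for the same sign and at least 50% of the size, which was met and goes against this explanation. Since the margin is smaller than that SD, the low values of that array may still carry much of the shift or little of it. The 2 cannot be told apart with the remaining arrays. An effect of tyrosol itself stays open as untested.

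The 6 arrays can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. By rank product the real split gave 216 probe sets, as large a count as in 1 of the 10, and the highest other gave 80; by limma it gave 76, again 1 of the 10, and the highest other gave 0. For the gene lists the real split gave 3 calls, 8 of the 10 gave as many, and the highest other gave 8. For the families it gave 5, 5 of the 10 gave as many, and the highest other gave 17. The 4 splits with both replicate 2 arrays on the same side gave 5 to 8 lists and 15 to 17 families, several times the real count of families, which points to a structure of the samples shared by those arrays; with the replicate number as a block the real split gave 4 lists and 7 families. Of the splits that part all 3 replicate pairs, as the real one does, the other 3 exchange control and tyrosol within 1 pair; they gave 0, 23 and 1 probe sets by rank product, 0 by limma, 0, 4 and 3 lists, and 1, 3 and 0 families.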

How the results depend on the processing

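Settings that leave out cross-hybridising probe sets, leave out both replicate 2 arrays or use the control transcripts' 3'-to-5' difference as a covariate, the family scan under other scalings, summaries or fry, the lists on centred arrays and the rank product on the mean of a gene's probe sets were chosen after seeing the data. The rank product count of 216 was 124 at a false discovery rate of 0.01, 108 without both replicate 2 arrays and 94 to 212 without single arrays, against 76 in limma; in the other settings it lay between 154 and 236, the latter with the replicate block. Limma's 76 became 163 with the replicate block, 208 with array weights, 50 without cross-hybridising probe sets and 0 to 84 without single arrays. The 3 called lists became 0 with an estimated correlation, 0 with fry, 6 in the upper part of mean levels, 7 with the covariate, 7 without both replicate 2 arrays and 3 to 7 without single arrays; sperm, body wall muscle and proteasome passed in each of the 15 settings with the preset correlation. The 5 families became 0 with an estimated correlation, 0 with fry, 12 with the covariate and 4 to 9 without single arrays. The fbxb family passed in 15 of 15 settings, msp in 14 of 14, ssp in 14, spig in 12 and fbxc in 8. The msp family could not be tested without cross-hybridising probe sets, since all its 23 genes are read on them. With the covariate immune effectors passed as lower (adjusted p = 0.00025) and insulin signalling and lifespan genes as higher (adjusted p = 0.029), and in the upper part of mean levels epidermis and pharynx passed as higher (adjusted p = 0.00067 and 0.0058). Cuticle collagens, at 0.0064 and not called, passed at -0.10 with the covariate (adjusted p = 0.015). Leaving out arrays lowers the number compared; the cause of the other shifts was not tested.

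Of 29 named genes that the rank product called, 16 to 24 were still called without single arrays, 21 without both replicate 2 arrays and 29 with the replicate block, with the sign kept in each; 26 sperm genes called higher became 20 to 26 without single arrays, 24 without both replicate 2 arrays and 1 of 44 without cross-hybridising probe sets. The replicate block, which gave 236 by rank product, changed list calls and rank product calls of named genes only as given with the comparisons, and brought the named genes under 0.05 in limma from 2 to 17 of the 29. No background level per array was available, so what low signals hide was not measured.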

Other observations

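The choice of the genes named here and the lists of zygotic embryo and male soma genes came after the results were seen. Outside the sperm list and the related msd genes, 120 genes rose, with a median difference of 0.87 on the log2 scale, and 117 of them had all tyrosol values above all control values. Limma called 48 of them, and 13 of the 120 were read on cross-hybridising probe sets. Several are known from embryonic development. The homeobox genes unc-39 (1.18), mls-2 (0.96), ceh-32 (0.83) and ceh-5 (1.38), the SoxB gene sox-2 (1.18) and the bZIP gene ces-2 (1.14) rose, as did hch-1 (1.11), whose product is needed for hatching, the junction gene dlg-1 (1.05) and the lipocalin gene lpr-3 (1.19), a matrix protein. The insulin-like peptide gene ins-2 rose by 1.37 (SE 0.13, limma adjusted p = 0.025), the cuticlin-like genes cutl-16 and cutl-9 by 1.43 and 1.41, and the F-box genes fbxb-88 and fbxb-102 by 0.93 and 0.67, with fbxb-101 and fbxb-66 called higher too. On cross-hybridising probe sets msd-4, related to the msp genes, rose by 0.87, and msd-2 was called higher too.

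The list of 71 zygotic embryo genes, written after this had been seen, had a mean difference of 0.22 and a median of 0.086, with 11 genes called higher and 48 above 0. Its level was above all controls on all 3 tyrosol arrays (two-sided exact permutation p = 0.1, the smallest possible), but the list holds genes that had prompted it, 17 of its members are also in a fixed list, and 45 lie above the median level of all genes. Of its 6 most abundant members in control worms, sqt-3 (9.57 in control worms and 9.67 in tyrosol worms), pal-1 (8.77 and 8.98), lin-26 (8.24 and 8.28), hmp-1 (8.09 and 8.18) and hmr-1 (7.66 and 7.60) were not called on the probe sets that represent them, and dlg-1 was (7.45, and 1.05 higher in tyrosol worms). Another probe set of sqt-3 was called higher (6.11 and 6.89), as were other probe sets of ajm-1 and eya-1. The list of 20 male soma genes had a mean of -0.040, with 0 genes called; its most abundant members, swm-1 (7.61 and 7.68) and gei-3 (4.83 and 4.87), differed by less than their standard errors.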
